A study of Mus musculus with 4 samples.

How the data were processed

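Libraries of 4 kinds were made from mouse ES cells: Esrrb ChIP-exo, Stat3 ChIP-exo, wild-type ATAC-seq and E2 delOS ATAC-seq, with 1 library each. The tools cutadapt, Bowtie2, Bowtie 0.12.7 and SAMtools and the builds mm9 and mm10 are named for the series, per the submitters' processing notes, which give no roles. The ChIP-exo lists were named by the authors as output of the caller GEM. Its settings are not given in the sources used here. Each event has a score in the deposited lists, which is the caller's own value and was used here only to rank and filter events within a list. Each event's name also holds the authors' rank and a k-mer, or dashes in its place. Esrrb events are 50 bp and Stat3 events 52 bp wide.

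ATAC-seq peaks were called with HOMER findPeaks, per the file headers, separately in each library, with a peak size of 150 bp, a false discovery rate of 0.001 and at least 4-fold density over the surrounding 10 kb. The signal of a peak is its tag count scaled to 10000000 total tags, per the file headers. The score is HOMER's own peak score, per the file headers. The fold of a peak over its local 10 kb and the Poisson p-value of that comparison were also deposited by the authors. The p-value was not used. Peaks needed at least 14 tags in the wild-type and 17 tags in the E2 delOS library, so the deeper library needed a lower density (3.29 against 4.15 scaled tags). The headers also give the maximum tags considered per bp, which was 1 in the wild-type and 2 in the E2 delOS library. Neither the handling of the Tn5 offset nor any removal of duplicate reads before peak calling is given in the sources used here.

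Builds were checked against the GRCm38.p6 gene table. No ChIP-exo event lay over 500 kb beyond the last gene of its chromosome, but 342 wild-type and 222 E2 delOS ATAC-seq peaks did. Events lay within 500 bp of a gene edge more often than after a move of 50 kb for Esrrb (5.85% against 2.63%) and Stat3 (10.0% against 2.91%), and about equally often for the ATAC-seq lists (3.97% against 3.77%, and 4.25% against 3.85%). The ChIP-exo coordinates were therefore taken as mm10 and the ATAC-seq coordinates as mm9. No coordinates were converted. Comparisons that join ChIP-exo with ATAC-seq, genes at ATAC-seq peaks and sequence windows around events were planned but not run, since no mm9 annotation and no genome sequence was used here. The authors' k-mers stood in for the sequence windows, a choice made after seeing the data. The gene table has no strand, so distances were taken from the gene's span in place of the planned start site.

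Events coincided when their midpoints lay within 100 bp. The background was 100 shuffles of the Stat3 events within chromosomes, and, added later, 100 moves by 1 to 10 kb. ATAC-seq peaks were matched by an overlap of at least 1 bp, against 100 shuffles. For tag ratios, shared peaks were each other's best overlap and covered at least 50% of each other. Such peaks passed the threshold in both libraries, which narrows the ratio for small peaks. The deviation of a peak is its log2 ratio minus the median of the 10% of shared peaks with similar mean tags. Tag density around a peak was its tag count divided by its fold. Each chromosome was split where 2 levels fitted best, with at least 100 peaks on each side. Medians have 95% bootstrap intervals from 1000 resamples of peaks, which are not replicates. A gene list's percentile is the share of 10000 random lists below it plus 50% of ties. The main statistic was the share of genes with an event, and the median number of events was added after the data had been seen.

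The 8 gene lists, the coincidence and overlap counts with their shuffles, the share of each gene list with its random lists, and the rule for named genes were fixed before the data were examined. Chosen after the data had been seen were the k-mer shares, the moves by 1 to 10 kb, the median number of events, both kinds of matching, the rank and score classes, and all tag ratios, deviations and chromosome splits of the ATAC-seq peaks. The rule names Klf4 and every event within 100 kb of it, 15 genes of the naive, core and LIF lists in list order, the 10 best-ranked ChIP-exo events of each list with their nearest gene, and the 10 highest-scoring peaks found in 1 ATAC-seq list only. Named outside the rule, after their values were seen, were Jak1, Socs3, Bcl3, Pou5f1, Tet2, Otx2, Tfap2c, Twist1 and Lum, and chromosomes 1, 8, 11, 14, 19 and X. The alternatives were other distances, windows and overlaps, the better-scoring 50% of each list, lists cut to equal length, peaks set to 500 bp, and the additions named in the closing section. Scripts were tested on simulated data. A planted share of 20.2% of 24616 events coinciding within 100 bp was returned as 20.2%. The planted share included background matches counted by the same distances, so this shows only that the planted events were found. For 300 events the nearest distance equalled that of a direct search. Planted steps of 0.5 (log2) were placed close to the planted point on 20 of 20 chromosomes, with noise independent between peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with seed 1.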

Results

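The data describe mouse embryonic stem (ES) cells of strain C57BL/6, grown without feeders in serum with LIF, the cytokine that acts through Stat3. Binding of Esrrb, an orphan nuclear receptor, and of Stat3 was mapped by ChIP-exo, in which an exonuclease trims the precipitated DNA up to the bound protein. Accessible chromatin was mapped by ATAC-seq, in which the Tn5 transposase cuts open DNA, in wild-type cells and in E2 delOS cells. In E2 delOS cells the composite Oct4/Sox2 motif of Klf4 enhancer E2 had been deleted on both alleles. The 4 groups had 1 library each, so no difference between libraries has a replicate check and no p-value is given. The exact 95% binomial intervals printed here cover counting error only. The ATAC-seq libraries held 33743952 tags in wild-type cells and 51635139 in E2 delOS cells, of which 6.16% and 3.08% lay in peaks. Groups follow the labels. In the ATAC-seq headers, however, the library name in the wild-type file holds an added code and that in the E2 delOS file holds none, which can be read as a swap of the 2 files. A swap would turn every direction between them and is not excluded. The depth of the ChIP-exo libraries is unknown.

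Esrrb was listed at 63628 binding events and Stat3 at 24616. Of the Esrrb events, 51.3% lay inside the span of a protein-coding gene and 85.5% within 50 kb of one. The values for Stat3 were 47.6% and 85.8%. A short sequence (k-mer) accompanied 73.4% of the Esrrb events (interval 73.1 to 73.8%) and 25.4% of the Stat3 events (24.9 to 25.9%). It was more frequent among weak events. The share was 58.8% in the best-ranked 10% of the Esrrb list and 87.0% in the last 10%. For Stat3 these shares were 18.0% and 43.1%. The commonest Esrrb k-mer was CAAGGTCA, at 14923 events, and the commonest Stat3 k-mer was TTCCTGGAA, at 974. The core of the Esrrb half-site, AAGGTCA on either strand, stood in the k-mer of 36.8% of all Esrrb events. The palindrome of TTC and GAA with 3 bases between, the usual Stat3 motif, stood in the k-mer of 4.90% of all Stat3 events. The sequence of the events themselves was not analysed here. The highest score was shared by 1489 Esrrb and 203 Stat3 events, which were ordered by the authors' rank number.

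The first comparison asked how often both factors were bound at the same place. Of the Esrrb events, 10826 had a Stat3 event within 100 bp, or 17.0% (interval 16.7 to 17.3%). Of the Stat3 events, 9728 had an Esrrb event within 100 bp, or 39.5% (38.9 to 40.1%). When the Stat3 events were placed at random within their chromosomes, the means were 0.203% and 0.497%, and the highest of 100 shuffles gave 0.252% and 0.605%. When they were moved by 1 to 10 kb, which keeps them in the same neighbourhood, the means were 0.727% and 1.76%. Neither background holds the events to accessible chromatin, and the planned one inside wild-type ATAC-seq peaks was not run. The excess therefore cannot separate a relation of these 2 factors from a common preference for accessible sites. Coinciding events lay a median of 27 bp apart counted from Esrrb and 24 bp counted from Stat3. The share of Esrrb events near Stat3 was 47.4% in the best-ranked 10% of the list and 4.84% in the last 10%. For Stat3 these shares were 70.7% and 18.97%. K-mers were less frequent where the factors coincided. They accompanied 43.3% of coinciding and 79.6% of separate Esrrb events, and 18.5% and 29.9% of the Stat3 events. The share was lower for coinciding events in each of 10 rank classes, for both factors.

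**Figure D1:**
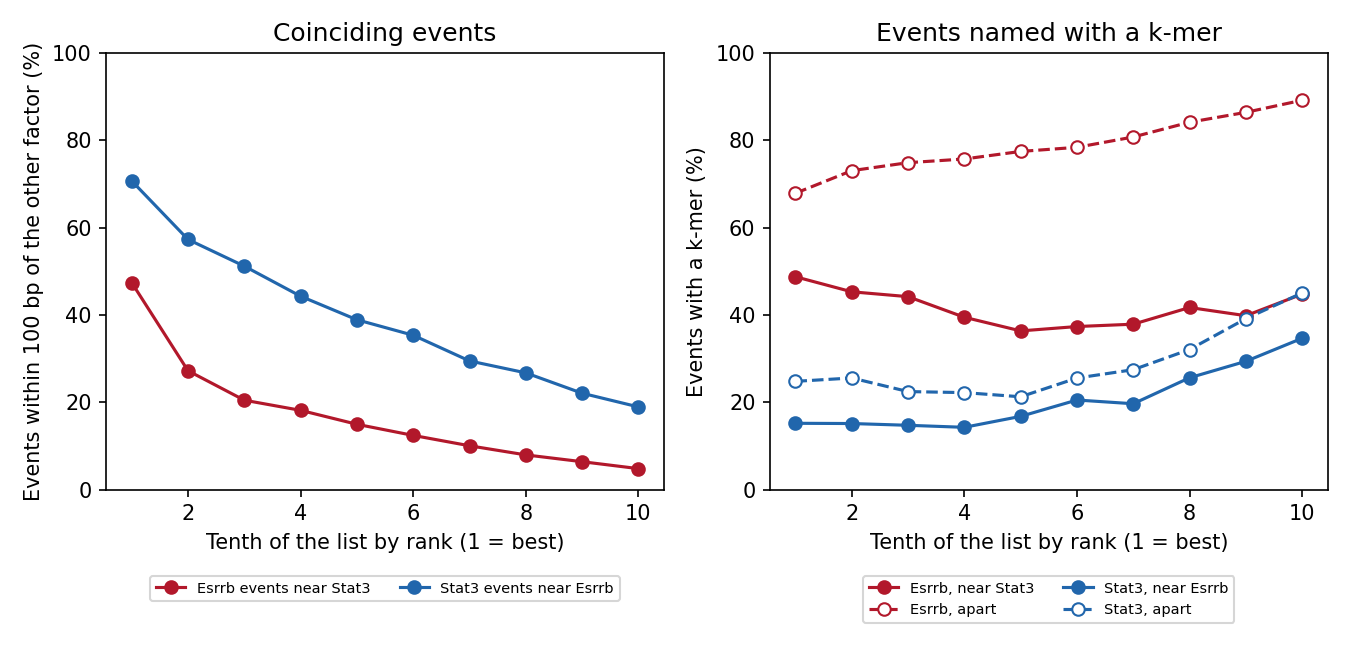
Left, the share of events (%) within 100 bp of an event of the other factor, against the tenth of the list by rank, for Esrrb (red) and Stat3 (blue). Right, the share of events (%) named with a k-mer, for coinciding (filled) and separate (open) events; coincidence falls from 47.4% to 4.84% for Esrrb and from 70.7% to 18.97% for Stat3.

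Events of both factors coincided at the Klf4 locus (chromosome 4, 55527137 to 55532475, mm10). Klf4 encodes a transcription factor of naive pluripotency. Within 100 kb of the gene there were 17 Esrrb events, 12 at lower and 5 at higher coordinates, and 6 Stat3 events, all at lower coordinates. The strongest were clustered about 50 kb from the gene. An Esrrb event at 55475635 to 55475684, ranked 35 in its list, lay 9 bp from a Stat3 event at 55475625 to 55475676, ranked 41. A second pair, both starting at 55475442, ranked 611 and 106. Another pair, at 55477466 and 55477449, ranked 390 and 165, at 49.6 and 49.7 kb from the gene. All 5 Esrrb events between 49.5 and 51.7 kb from the gene lay within 62 bp of a Stat3 event. The Stat3 events at 55464158 and 55464316, ranked 326 and 444, had no Esrrb event closer than 3848 bp. None of the 6 Stat3 events had a k-mer. Of the 17 Esrrb events 10 had a k-mer, none of them among the 5 that coincided with Stat3. Nearest to the gene were Esrrb events at 1.28 and 2.00 kb, ranked 14145 and 21731. The labels give no coordinates for enhancer E2, so no event was assigned to it.

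**Figure D2:**
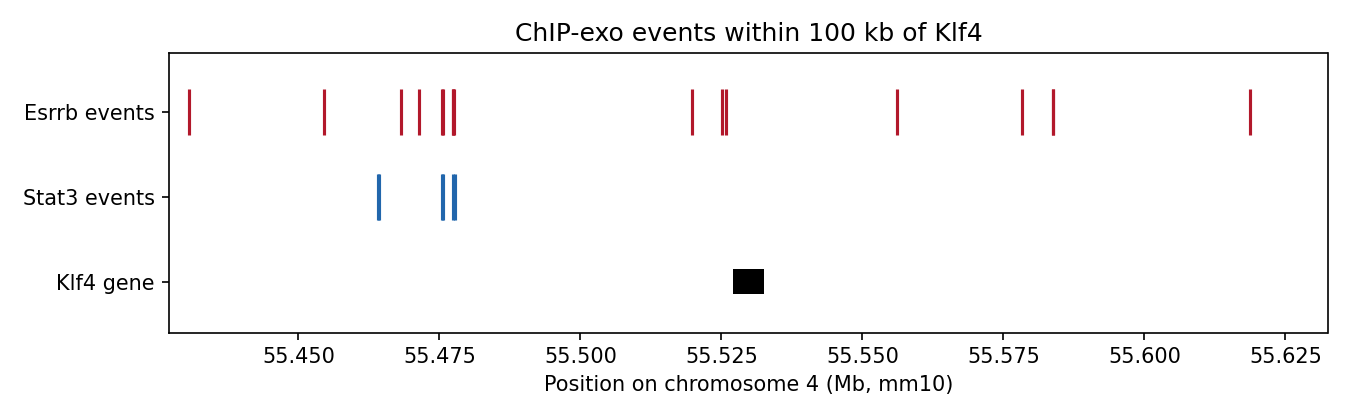
Positions (Mb on chromosome 4, mm10) of the 17 Esrrb events (red) and 6 Stat3 events (blue) within 100 kb of the Klf4 gene (black bar). Each tick is 1 event, and ticks of events close together merge; the 6 Stat3 events all lie at lower coordinates than the gene.

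The gene lists, fixed before the data were examined, were compared with 10000 random lists of protein-coding genes of the same size. Each of the 15 naive pluripotency genes had both an Esrrb and a Stat3 event within 50 kb. The share stood at percentile 97.3 for Esrrb, where random lists averaged 82.4%, and at 99.8 for Stat3, where they averaged 70.1%. The 12 core pluripotency genes also all had both, at percentiles 95.2 and 99.5. Of the 12 genes of the LIF and Stat3 pathway, 12 had an Esrrb event (percentile 95) and 11 a Stat3 event (95.2). The exception was Jak1, the kinase that phosphorylates Stat3. The share was near its ceiling for Esrrb: 82.2% of 21631 protein-coding genes had an Esrrb event within 50 kb and 70.0% a Stat3 event. The 10 housekeeping genes reached percentiles 93.3 and 91.0, close to those of the LIF list. Primed pluripotency genes stood at 66.3 and 88.0, early lineage genes at 85.9 and 60.5, trophoblast genes at 84.6 and 73.5, and fibroblast or feeder genes at 40.2 and 9.73. The Esrrb share was 100% for housekeeping and trophoblast genes too, as for the naive, core and LIF lists. Esrrb percentiles of lists at 100% differed only through the number of genes and the random draws. In the better-scoring 50% of the Stat3 list, random lists averaged 50.9 to 51.3%. There the share was 93.3% for naive, 100% for core, 91.7% for LIF and 80% for housekeeping genes (percentiles 99.97, 100, 99.8 and 96.1). It was 55.6% for primed, 46.7% for early lineage, 50% for trophoblast and 20% for fibroblast or feeder genes (59.6, 37.0, 48.2 and 2.63). With random lists matched on the number of events of the other factor, the naive list stood at percentiles 60.2 and 66.9, the core list at 50.8 and 69.0 and the LIF list at 74.1 and 22.2. The matched lists averaged 96.0 to 99.9% for Esrrb and 96.3 to 97.4% for Stat3. A share of 100% could stand no higher against them, so this matching left almost no room for an excess. Only the Stat3 share of the LIF list, 91.7%, lay below its matched mean of 96.3%.

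Because the share left little room, the median number of events per gene was added after the data had been seen. It was 18 for Esrrb and 9 for Stat3 in the naive list, 18 and 10 in the core list, and 15 and 10 in the LIF list, against 5 and 2 over all protein-coding genes. These medians lay above those of nearly all random lists (percentile 100 each). Primed pluripotency genes stood at percentiles 97.6 and 96.6 on this measure, and housekeeping genes at 92.7 and 97.95. With random lists matched on the events of the other factor, the naive, core and LIF lists stood at 92.0, 85.0 and 46.7 for Esrrb and at 99.2, 99.7 and 99.95 for Stat3. Among naive genes, Prdm14 had 30 Esrrb and 14 Stat3 events, the Esrrb gene itself 27 and 18, and Tfcp2l1 25 and 9. Klf5, Nanog and Tbx3 had 23 Esrrb events each, with 15, 13 and 13 Stat3 events. Fgf4 had 22 and 8, Dppa3 18 and 6, Klf2 15 and 10, Zfp42 15 and 7, Gbx2 12 and 9, and Nr5a2 11 and 7. The fewest were at Klf4 (8 and 2), Nr0b1 (7 and 2) and Tcl1 (6 and 1). The window of Klf4 ended at 50 kb and so left out the pairs at 51.5 and 51.7 kb.

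**Figure D3:**
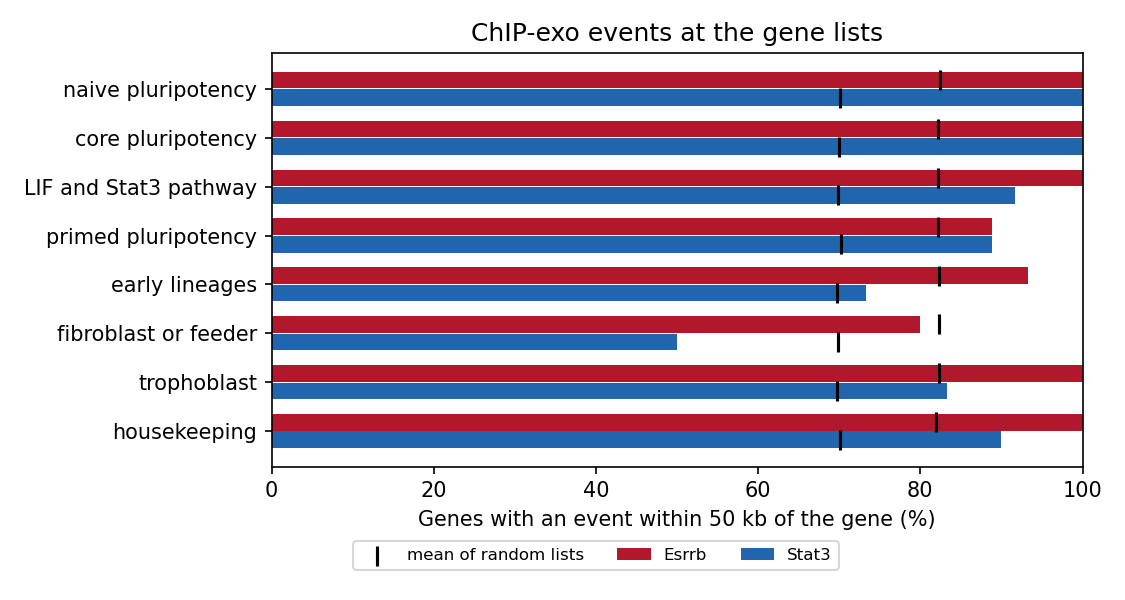
Share of the genes of each list (%) with an Esrrb (red) or Stat3 (blue) event within 50 kb of the gene. Black ticks mark the mean of 10000 random lists; the naive and core lists reach 100% for both factors and the fibroblast or feeder list 80% and 50%.

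The 10 best-ranked events of each list had no gene of the pluripotency lists as their nearest gene, although other events with the same highest score lay near such genes, Klf5 and Esrrb among them. Of the 10 best-ranked Esrrb events, 5 lay between 98662733 and 98667282 of chromosome 2, 1031 kb or more from the nearest protein-coding gene, Lrrc4c. Of the 10 best-ranked Stat3 events, 6 lay between 98662396 and 98667289. The others were nearest to Rpusd4, Chl1, Ly6c2, Esp38 and Gm2244 for Esrrb, and to Rpusd4, Esp38 and Pak3 for Stat3. None of these 20 events had a k-mer, and 8 of the 10 Esrrb and 9 of the 10 Stat3 events lay within 100 bp of the other factor. The counts were the same, 8 and 9, for the 10 best-ranked events with a k-mer. In both ATAC-seq lists, too, the peak with the most tags lay on chromosome 2, at 98507218 to 98507368 (mm9). A peak at 98506697 to 98506847 was among the 5 highest in both. Coordinates were not converted between builds, so whether the events and these peaks share 1 place was not tested. Strong signal of every library there, in place of binding, is not excluded.

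The second comparison asked how accessible chromatin differed between the genotypes. Wild-type cells had 61127 peaks and E2 delOS cells 42972, of which 2885 and 2105 entries repeated an interval already listed. Of the wild-type peaks, 32982 overlapped an E2 delOS peak, or 54.0% (interval 53.6 to 54.4%), and 28145 did not. Of the E2 delOS peaks, 32443 overlapped a wild-type peak, or 75.5% (75.1 to 75.9%), and 10529 did not. Shuffled peaks overlapped in 0.470% and 0.666%. No E2 delOS peak lay within 1 kb of 20746 wild-type peaks, and no wild-type peak within 1 kb of 7171 E2 delOS peaks. Absence followed the score: it was 2.21% in the highest-scoring 10% of the wild-type list and 82.1% in the lowest, and 1.35% and 67.1% for the E2 delOS list. The caller's local filter had removed 37.7% of candidate peaks in wild-type cells and 66.8% in E2 delOS cells.

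**Figure D4:**
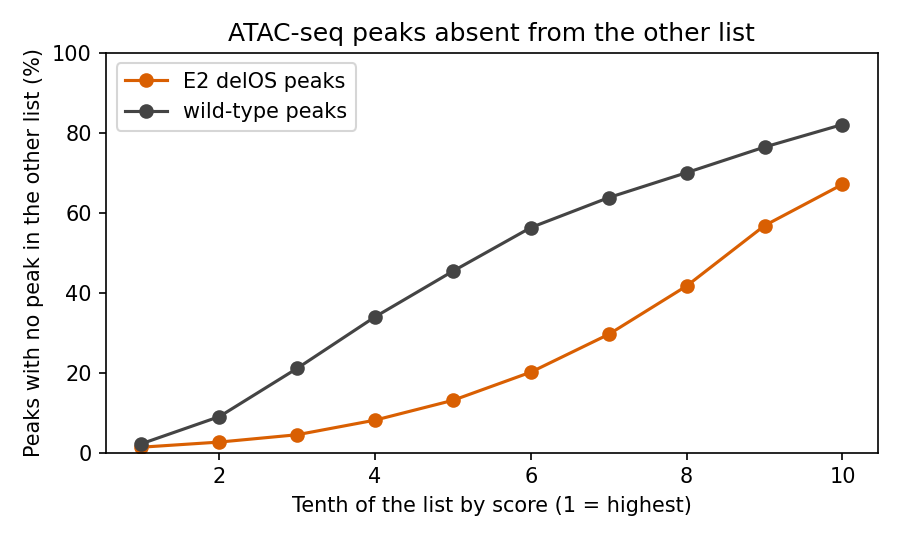
Share of ATAC-seq peaks (%) with no overlapping peak in the other list, against the tenth of the list by score (1 is the highest), for wild-type and E2 delOS peaks. For wild-type peaks it rises from 2.21% to 82.1%.

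In the 25843 peaks shared by both lists, tags scaled to 10000000 total tags per library were lower in E2 delOS cells at 94.4% of peaks, with a median log2 ratio of -0.71 (bootstrap interval -0.72 to -0.71). The E2 delOS library also had the lower share of tags in peaks. Relative to the typical ratio of peaks of the same size, 289 peaks were over 2-fold higher and 213 over 2-fold lower, together 1.94% of shared peaks. The median counting error of a peak's log2 ratio was 0.36, and the standard deviation of the deviations was 0.41. Counting error could thus make up much of the spread. Segments of 2 chromosomes stood apart. On chromosome 8, 345 shared peaks from 105308237 to 131671318 (mm9) had 1.54-fold the typical ratio, a log2 deviation of 0.62 (0.57 to 0.66), while the ratio itself was -0.17 (-0.21 to -0.12). On chromosome 14, 327 shared peaks from 73247459 to 125074385 had 0.714-fold, a deviation of -0.49 (-0.56 to -0.45), with a ratio of -1.25 (-1.30 to -1.16). The best split of the other 18 chromosomes gave steps of up to 0.23. Chromosome X as a whole deviated by -0.20 (-0.24 to -0.16) and chromosome 11 by 0.11 (0.09 to 0.13). The 10 highest-scoring wild-type peaks without an E2 delOS peak within 1 kb held 24.2 to 58.7 scaled tags, and 4 of them lay in the first 3.5 Mb of chromosome 11. The 10 such E2 delOS entries, 9 of them distinct intervals, held 9.39 to 13.0. In each list, 8 of the 10 had a peak of the other list within 5 kb. Their fold over the local 10 kb was 4.17 to 9.32 for the wild-type and 4.1 to 5.33 for the E2 delOS entries, where the caller required at least 4. Genes at ATAC-seq peaks, Klf4 among them, were not analysed here, because these coordinates fit another genome build than the gene table.

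**Figure D5:**
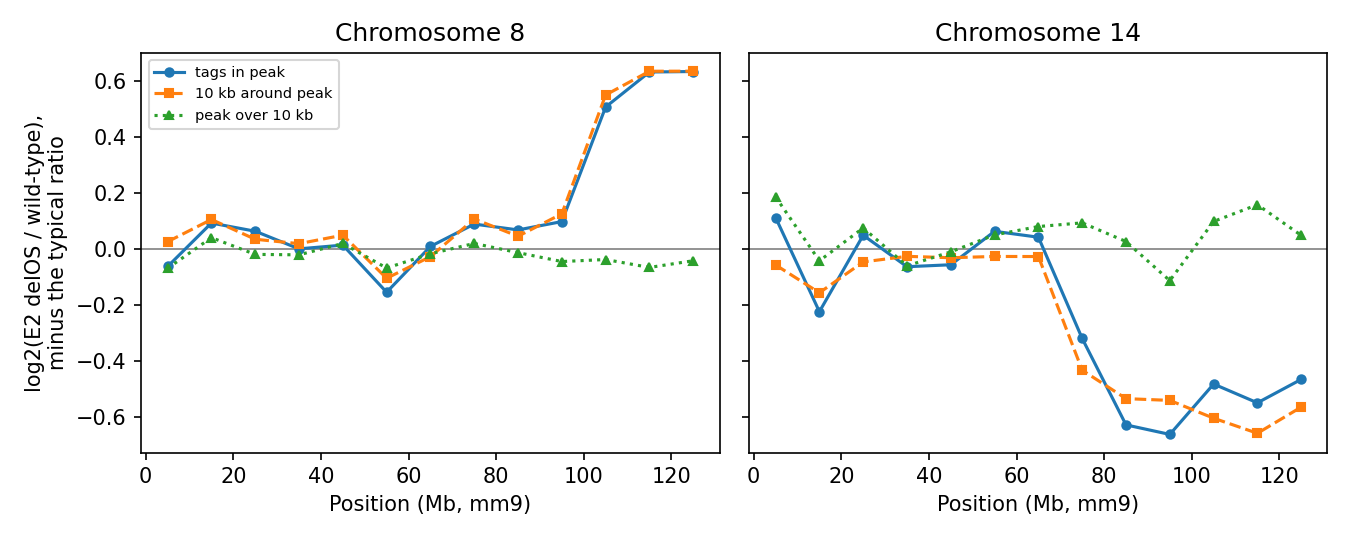
Median log2 ratio of E2 delOS to wild-type in shared ATAC-seq peaks, minus the typical ratio, in 10 Mb bins of chromosomes 8 and 14 (Mb, mm9). Lines show tags in the peak, the 10 kb around it, and the peak over its 10 kb; tags in the peak lie at 0.62 relative to the typical ratio on distal chromosome 8 and at -0.49 on distal chromosome 14.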

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

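With 1 library per group, a share counts here as moved when it left the counting interval of the main value, so small shifts of large lists count. A percentile was judged by the counting interval over its 10000 random lists, and the median tag ratio by its bootstrap interval. The number of events in a list was judged by a fixed factor. Backgrounds of coincidence were run at 100 bp only. For Esrrb and Stat3 coincidence was 12.5% and 31.2% at 50 bp, 23.6% and 48.1% at 500 bp, 18.5% and 42.5% in the better-scoring 50% of each list, and 15.8% and 37.5% outside crowded windows, an alternative chosen after seeing the data. That 50% holds 31814 Esrrb and 12308 Stat3 events by construction. Counting only k-mers with the exact core, also chosen later, left 36.8% and 4.90% of events. ATAC-seq overlap depended on its definition. For wild-type and E2 delOS peaks it was 46.5% and 65.6% at reciprocal 50% overlap, 66.1% and 83.3% within 1 kb, 62.5% and 88.4% in the better-scoring 50%, 63.2% and 82.1% with 500 bp peaks, 66.8% and 67.5% with lists of equal length, and 53.5% and 75.0% with each interval counted once, chosen after seeing the data. The median log2 tag ratio was -0.97 in the highest-scoring 10% of wild-type peaks.

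Lists of 6 to 15 genes have wide counting intervals, so a loss of several genes can stay inside them while a gain of 1 gene near the ceiling does not. Lower but inside their intervals were these shares. For Stat3 in the better-scoring 50% they were 93.3% for naive, 55.6% for primed, 46.7% for early lineage, 50% for trophoblast, 20% for fibroblast or feeder and 80% for housekeeping genes. For Stat3 at 20 kb they were 86.7% for naive, 60% for early lineage, 50% for trophoblast and 40% for fibroblast or feeder genes. For Esrrb they were 80% for early lineage and 60% for fibroblast or feeder genes in the better-scoring 50%, and 77.8% for primed, 80% for early lineage, 83.3% for trophoblast and 70% for fibroblast or feeder genes at 20 kb. Shares left their intervals in these cases: within 100 kb, 100% of primed and early lineage genes had an Esrrb event, and 100% of LIF, 93.3% of early lineage and 100% of trophoblast genes a Stat3 event. Percentiles of the share for the naive, core and LIF lists were, for Esrrb, 99.6, 99.1 and 99.0 at 20 kb, 92.2, 88.5 and 88.4 at 100 kb, 99.7, 99.3 and 99.3 in the better-scoring 50%, 96.6, 98.9 and 94.1 when matched on gene span, and 60.2, 50.8 and 74.1 when matched on Stat3 events. For Stat3 they were 99.4, 99.96 and 99.5 at 20 kb, 98.0, 96.1 and 96.0 at 100 kb, 99.97, 100 and 99.8 in the better-scoring 50%, 99.7, 99.8 and 94.0 when matched on gene span, and 66.9, 69.0 and 22.2 when matched on Esrrb events. Percentiles of the median number of events were 99.8 for the LIF list and Esrrb at 20 kb, and with that matching 92.0, 85.0 and 46.7 for Esrrb and 99.2, 99.7 and 99.95 for Stat3. Both kinds of matching, and the median, were chosen after seeing the data. For Esrrb, the shares of the naive, core and LIF lists stayed at 100% in every setting. Their percentiles of the share therefore moved only with the random lists, and a share of 100% could stand no higher against each. The cause of the other shifts was not tested. For the other 5 lists, 94 of 100 such percentiles moved. That interval over the 10000 random lists is narrow and leaves out the counting error of the few genes in a list. Not run were the alternatives for ATAC-seq at Klf4, ChIP-exo inside ATAC-seq peaks, absence by bound factor, ATAC-seq gene lists and sequence windows, for want of a shared build or a genome.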

Other observations

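All tests in this part were chosen after the data had been seen. Only the prediction for crowded windows was set before its result was seen. Directions between the ATAC-seq libraries hold only if the files are labelled correctly, which the names in their headers put in doubt.

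The genes named in this paragraph were chosen after their values were seen. Socs3, the feedback inhibitor of LIF signalling, had 28 Stat3 and 29 Esrrb events within 50 kb, the most Stat3 events of any gene in the 8 lists. Bcl3 had 19 Stat3 events, and Pou5f1 and Tet2 17 each. Among genes of other states, Otx2 had 19 Esrrb events, with the best ranked 84, and Tfap2c had 23, with the best ranked 334. Twist1 and Lum had no event of either factor.

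Relative to the typical ratio, E2 delOS tags were higher on distal chromosome 8 and lower on distal chromosome 14. The log2 ratio itself was -0.17 and -1.25 there, against -0.71 over all shared peaks. Peaks alone becoming more or less accessible is argued against by the surrounding 10 kb, which deviated from its typical ratio by 0.62 and -0.56 (log2), as far as the peaks. The lower share of tags in peaks of the E2 delOS library is argued against on chromosome 8, since steps on the other 18 chromosomes were up to 0.23. A copy number difference between the cell lines is a candidate explanation, since the ratio of peak to surroundings moved by -0.0447 and 0.0531 (log2). This is not separate evidence, because the density of the 10 kb was derived from the tags and this ratio. Shared peaks had also passed the 4-fold local filter in both libraries, which limits how far this ratio could fall. An even change in Tn5 cutting over the whole segment stays open, as does which line differs from the normal state, and nothing here ties the segments to the edited enhancer.

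Coinciding Esrrb events had fewer k-mers. The score is argued against as the whole cause, since the difference was 36.3 percentage points over all events and the difference averaged 37.2 points within rank classes. Crowded regions stay open: outside windows with 10 or more events in 10 kb the difference was 35.4 points, but these held 3.12% of the events, too few to bring it below 26.6. Binding through another protein, and signal common to any library of these cells, cannot be told apart, because no control list was used here. Of the coinciding Esrrb events, 49.3% had no k-mer in either list.

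For wild-type peaks absent from the E2 delOS list, the lower share of tags in peaks of that library and a change in accessibility cannot be told apart. In the highest-scoring 10%, 2.21% were absent, but the threshold of a list lowers absence at high scores in either direction: of E2 delOS peaks, 1.35% were absent from the wild-type list there. At the median log2 ratio over all shared peaks, -0.71, 50.3% of the absent peaks would fall below the E2 delOS tag threshold. Another 1374 were at least 2 times above it at that ratio, of which 706 had no E2 delOS peak within 1 kb. These values rest on that 1 ratio, which was -0.21 in the 10% of shared peaks with the fewest wild-type tags and -1.01 in the 10% with the most. As large peaks had lower ratios, 1374 and 706 are likely too high. The local filter, which removed 66.8% of E2 delOS candidates, was not taken into account. A change in accessibility at these 1374 peaks caused by the deletion stays open, as genotype and library cannot be separated with 1 library each.

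On chromosomes 1, 8, 11 and 19, 28.0%, 24.7%, 20.5% and 21.0% of E2 delOS peaks had no wild-type peak within 1 kb, against a median of 14.3% over the other 16 chromosomes. Wild-type peaks without an E2 delOS peak within 1 kb made up 38.5%, 35.8%, 41.3% and 41.6% there, against a median of 32.1% and a maximum of 37.8% over the other 16, so that chromosome 8 did not stand apart in this share. The highest candidate number per Mb was above that of the other chromosomes in both libraries, at 52.6, 54.4, 110 and 81.7 against a median of 29.9 in the wild-type and 78.0, 118, 218 and 130 against 30.0 in the E2 delOS library.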
